A study of Sus scrofa with 16 samples.

How the data were processed

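RNA sequencing of pig whole blood, named cord blood in the title of the series, was deposited for 16 libraries in 4 groups of 4: control, dichloroacetate (DCA, an inhibitor of pyruvate dehydrogenase kinase), Staphylococcus epidermidis (SE), and both together (SE+DCA). The labels give the bacterial dose as 500000 CFU per ml, while the dose of DCA and the times of exposure are not given in the sources used here. RNA was isolated with an RNeasy Lipid Tissue Mini Kit, and Novogene prepared the libraries and sequenced paired 150-bp reads on a NovaSeq instrument. The deposited values are raw counts of reads per Ensembl gene in 31907 gene entries, followed by 5 summary entries for reads assigned to no single gene. Per the labels the authors used Trim Galore, HISAT2, HTSeq and DESeq2 with the pig genome Sscrofa11.1, and the versions, the strand setting and the annotation release are not given in the sources used here. The summary entries were left out of every total.

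Gene symbols were taken from the identifiers through a reference table, which named 15029 of the 31907 identifiers. Gene positions and spans came from the RefSeq genes of Sscrofa11.1, matched by symbol. TNF, IL1B and SLC2A1 had no entry under their symbol and were not analysed here. Total counts ran from 8385451 to 14524692 per library. A single gene without a symbol took 67.45 to 83.5% of these counts, which left 1453000 to 3920000 counts per library for the other genes. A count of 0 allowed for up to 3 counts, which was 0.153 to 0.571 CPM (counts scaled to library size) depending on the library. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group were copies of each other, as the lowest chi-square per degree of freedom between replicates was 10.54.

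Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which kept 7569 genes, of which 6794 had a symbol. Library sizes were scaled by trimmed mean of M values (TMM), with factors from 0.46 to 2.14, and CPM values use the scaled sizes. The groups were fitted in 1 robust quasi-likelihood model of the 16 libraries with a common dispersion of 0.181, and 5 contrasts were tested two-sided: SE versus control, DCA versus control, SE+DCA versus SE, SE+DCA versus DCA, and the interaction of SE and DCA. P-values were adjusted by Benjamini-Hochberg over the tested genes of a contrast, with a threshold of 0.05. Fold changes are on the log2 scale with a standard error (s.e.). This was derived from the fold change and the F statistic of its quasi-likelihood test, so it is approximate. CPM values are means with their standard deviation (SD, n = 4 libraries per group).

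The titles give a pig letter (B, E, H or L) that recurs in each group, so libraries that share a letter were taken as coming from 1 animal. The letter was left out of the model and entered as a replicate block as an alternative, with which SE versus control had 16 genes past the threshold against 18 without it. The deposited identifiers also carry a technical letter after the library number, called the library mark here, which was a for 5 libraries (SE B, SE H, SE L, control H and DCA E) and r for the other 11.

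Lists of genes for 36 pathways, responses and cell types were fixed, and the 33 with at least 4 tested members were tested. The test was camera of limma 3.58.1 with a preset correlation of 0.01, two-sided and adjusted over 165 tests, and beside it camera with an estimated correlation and fry. The count of list members past the gene test is given over all genes and adjusted over the list alone. The groups, contrasts, gene lists, alternatives in the processing and the rule for named genes were fixed before the data were examined. By that rule, the named genes are those with the 8 largest rises and the 8 largest falls past the threshold with a symbol, a mean of at least 5 CPM and the same sign in 4 letters. To these come up to 4 members with the lowest p of each described list, and 12 fixed genes. Genes past the threshold outside the rule are named where stated, after their values were seen, and list members named beyond the 4 with the lowest p were chosen in the same way.

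Measures of single libraries were compared by exact permutation tests, two-sided, for which 4 against 4 libraries cannot go below p = 0.0286. The alternatives were the replicate block, DESeq2 1.42.0 with and without the block, size factors by relative log expression, library size alone, no filter and a stricter filter of 1 CPM in at least 8 libraries. Others were a fit of only the 2 groups compared, an adjusted p under 0.10, a fold change of at least 1.5, removal of haemoglobin and erythroid genes, the library mark or the haemoglobin share as a covariate, and leaving out each letter and each library. Alternatives chosen after seeing the data were a block with the letters of 2 DCA libraries exchanged (the crossed block), that block with the mark, the libraries of 1 mark alone, removal of the most abundant gene, and 2 averaged contrasts. The procedure was tested on simulated data with 220 changed genes among 7569: edgeR recovered 6.9% of 2-fold, 50.7% of 4-fold and 86.4% of 8-fold changes with 6.73% false calls, and DESeq2 recovered 20.7%, 59.7% and 89.4% with 15.8% false calls. The simulated counts held no difference between marks or letters and no correlation between genes. These rates therefore need not hold for the real libraries.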

Results

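To determine how pig cord blood responds to Staphylococcus epidermidis (SE), a skin bacterium that infects preterm newborns, RNA was sequenced from 16 libraries. Dichloroacetate (DCA), which blocks pyruvate dehydrogenase kinase, was added with and without the bacteria, giving 4 groups of 4 (control, DCA, SE and SE+DCA). Each group held the pig letters B, E, H and L. The libraries held 8385451 to 14524692 counts, of which the genes other than the most abundant one took 1453000 to 3920000. Haemoglobin genes took 18.9 ± 6.18% (SD, n = 16) of those remaining counts. The first principal component held 37.1% of the variance and the second 9.5%. The 5 libraries with mark a had a mean of 47.96 on the first component (14.9 to 83.9) and the 11 with mark r a mean of −21.8 (−50.5 to 12.1; p = 2.29e-04, exact permutation test, the smallest that 4368 splits can give). Of 12 genes that part the letters B and E in the other groups, 11 placed DCA B with letter E and 11 placed DCA E with letter B. In the other 46 such placements 39.3 to 100% of the genes stood with the library's own letter, the lowest being SE B against H. The sign in 4 of 4 letters that is given below for DCA contrasts was the same with these letters exchanged.

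**Figure D1:**
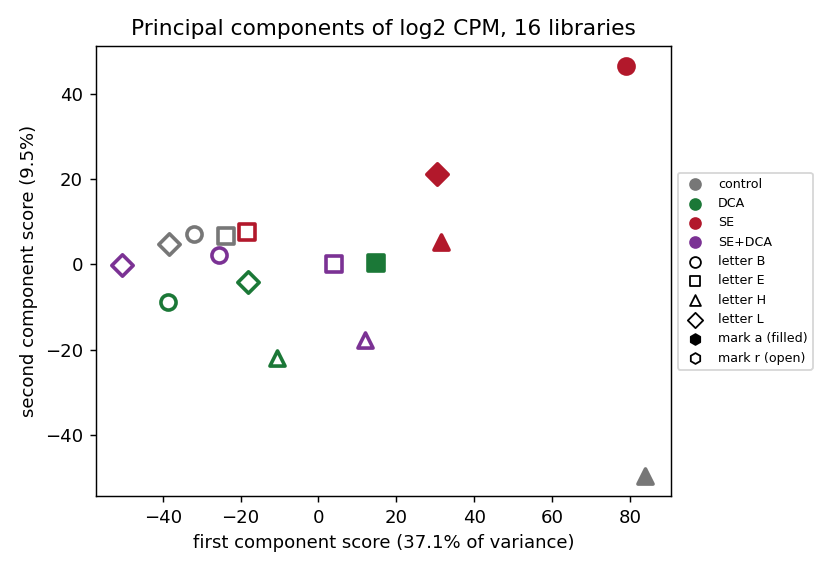
Scores of the 16 libraries on the first (37.1% of variance) and second (9.5%) principal components of log2 CPM, with the group as colour, the pig letter as shape and the library mark as filled (a) or open (r) symbols. The 5 libraries with mark a lie at higher scores on the first component than the 11 with mark r.

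Libraries with mark a, which were 3 of the 4 SE libraries, 1 control and 1 DCA library, differed from the others in gene content. The most abundant gene took 71.12% of counts against 79.47% (permutation p = 0.00137, adjusted p = 0.00548). This left a mean of 3466000 against 2118000 counts for the other genes (permutation p = 4.58e-04, adjusted p = 0.00412). Ribosomal protein genes took 10.72% of the remaining counts against 8.906% (permutation p = 6.87e-04, adjusted p = 0.00412). Haemoglobin genes with a symbol took 24.7% against 16.29% (permutation p = 0.00641, adjusted p = 0.0192). Genes of the mitochondrial genome took 0.61% against 1.414% (permutation p = 0.0151, adjusted p = 0.0362). These permutations left the groups aside, so they cannot part the mark from SE. With the mark and the crossed block in the model, 518 genes were higher and 295 lower in mark a. Among them were NOP10, a component of small nucleolar particles (log2 difference 2.29), RPLP2, a ribosomal protein (2.15), and ATP5IF1, an inhibitor of the mitochondrial ATPase (2.12). Lower were MAP3K3, a kinase of stress signalling (−2.46), KDM6B, a histone demethylase (−2.26), and BTG1, an inhibitor of proliferation (−2.08). The medians of the ribosomal protein list, the nuclear-encoded oxidative phosphorylation list and the granule list were 1.04, 1.03 and 1.03 higher in mark a, and that of the erythroid list 0.58 higher. The mitochondrial list had a median difference of 0.01 in this model, which holds the groups, with 0 genes called.

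To determine what the bacteria changed in blood without DCA, SE was compared with control. Genes of chemokines and of NF-kB feedback rose. GPR84, a receptor for medium-chain fatty acids on activated myeloid cells (chromosome 5, 19552828 to 19554848), rose from 1.29 ± 0.568 to 30 ± 6.81 CPM (SD, n = 4), with a log2 fold change of 4.51 ± 0.38 s.e. (adjusted p = 6.93e-07). G0S2, an inhibitor of the lipase that releases fatty acids from stored fat (chromosome 9, 133287065 to 133288066), rose from 1.15 ± 0.49 to 34.6 ± 12.8 CPM (log2 4.88 ± 0.55, adjusted p = 5.61e-05). CSF1, the growth factor of monocytes and macrophages (chromosome 4, 110178466 to 110198232), rose from 1.19 ± 0.618 to 21.9 ± 9.77 CPM (log2 4.26 ± 0.51, adjusted p = 9.12e-05).

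The chemokine genes CCL3L1 and CCL4, which lie side by side on chromosome 12 and draw monocytes and lymphocytes, rose by 4.21 ± 0.57 and 3.25 ± 0.45 (log2, adjusted p = 4.56e-04 and 4.24e-04). CCL4 went from 4.17 ± 1.65 to 40 ± 8.32 CPM. ICAM1, an adhesion molecule, rose by 3.75 ± 0.52 (adjusted p = 4.24e-04), and IER3, an early response gene that limits cell death, by 3.59 ± 0.37 (adjusted p = 1.35e-05). NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, rose from 10.9 ± 3.65 to 63.8 ± 9.27 CPM (log2 2.54 ± 0.35, adjusted p = 4.24e-04). These 8 genes had the 8 largest rises under the rule and were higher with SE in 4 of 4 letters. In total, edgeR called 18 genes, 17 higher and 1 lower. At the same time, 601 genes had an unadjusted p under 0.05 where 378 were expected by chance. With the mark as covariate this number was 322, below the 378, and it was 334 with the mark and the crossed block. It was 189 without letter B, 201 without letter L and 1723 without control H.

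The other 10 called genes were not among the largest changes under the rule. Some of them come under it as members of described lists with the lowest p, and the rest are named after their values were seen. DUSP2, a phosphatase that switches off MAP kinases, rose by 2.19 ± 0.34 (log2, adjusted p = 0.00125). Also higher were the NF-kB inhibitors NFKBIE (1.87) and NFKBID (1.70), the survival gene BCL2A1 (2.31), TAGAP (1.55), DDIT4, a stress-induced inhibitor of mTOR (1.62), the chemokine CCL2 (3.65), the cytokine IL1A (4.90) and ENSSSCG00000039214 (5.68). The gene that fell was NMD3, an export factor of the large ribosomal subunit (−2.49 ± 0.51, adjusted p = 0.0385). IL1A had 4 counts in the control libraries against 116 in the SE libraries, so its fold rests on few counts. ENSSSCG00000039214 had 14 counts in the control libraries, each from control E, against 619 in the SE libraries. Its log2 fold change ran from 5.16 to 10.31 over 30 settings. NMD3 had 13 counts in the SE libraries against 93. With the replicate block 16 genes passed, all of them higher. NMD3 and CCL2 did not (adjusted p = 0.0809 and 0.125, and 0.00468 to 1 for each over its settings). NMD3 was lost in 21 of 29 settings, CCL2 in 17 of 25, TAGAP in 19 of 30, DDIT4 in 16 of 30 and NFKBID in 12 of 30.

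**Figure D2:**
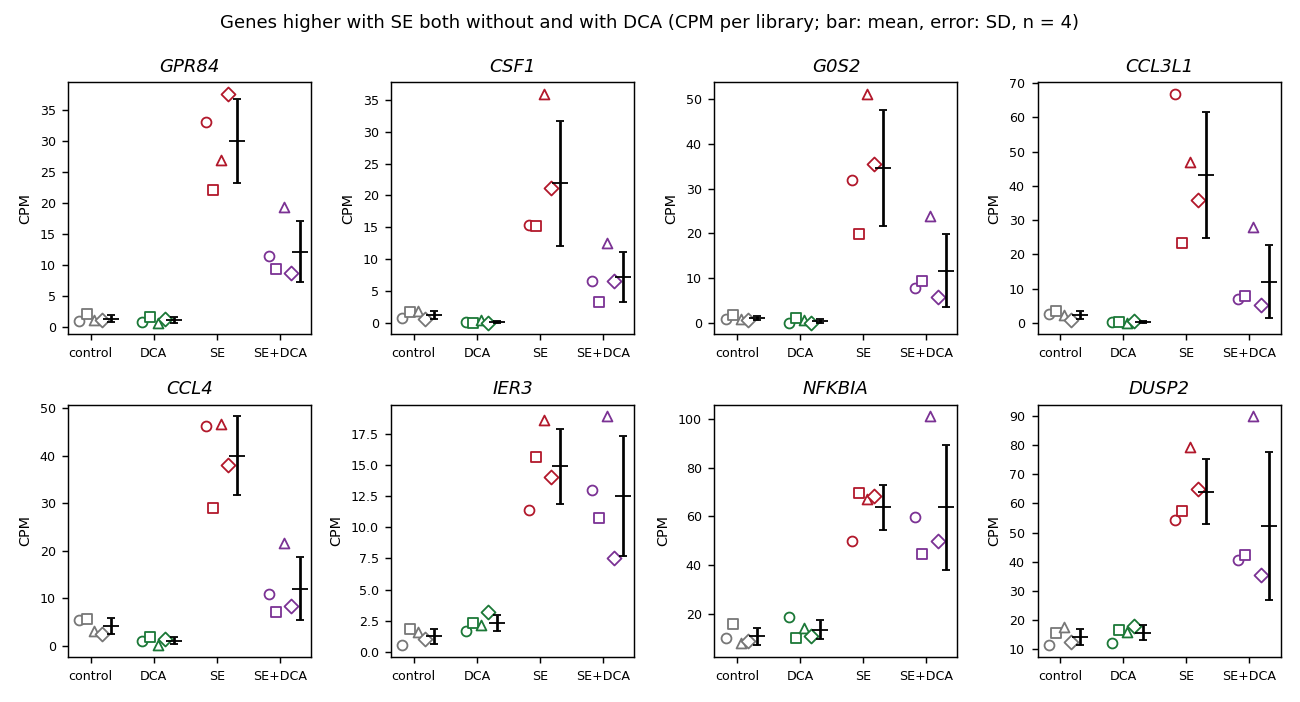
Expression in CPM of GPR84, CSF1, G0S2, CCL3L1, CCL4, IER3, NFKBIA and DUSP2 in the 16 libraries by group, with points for libraries and bars for the mean and SD (n = 4). GPR84 reached a mean of 30 CPM with SE and 12.2 CPM with SE+DCA, against 1.29 in control and 1.07 with DCA.

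By gene list, 5 of the 8 tested proinflammatory cytokine and chemokine genes rose (CSF1, CCL3L1, CCL4, IL1A and CCL2), 6 adjusted over the list alone. The list's median was 3.45 (adjusted p = 1.31e-23, adjusted p = 1.93e-04 with an estimated correlation). Of 18 feedback inhibitors of inflammatory signalling 3 rose (NFKBIA, NFKBIE and DUSP2), with 8 higher and 1 lower adjusted over the list alone. The median was 0.82 (adjusted p = 1.63e-09, adjusted p = 0.012 with an estimated correlation). Of 17 apoptosis and p53 targets 1 rose (BCL2A1), 3 adjusted over the list alone, with a median of 0.47 (adjusted p = 0.0159, adjusted p = 0.187 with an estimated correlation). That call was lost without letter E (adjusted p = 0.365), without letter H (0.2) and by library size alone (0.0668). The Toll-like receptor and NF-kB list missed the threshold of the list test, and no member was called over all genes. Among members that were higher, values were 2.18 ± 0.73 for TLR2, the receptor of bacterial lipoproteins (adjusted p = 0.526), 2.10 ± 0.71 for MAP3K8 and 1.08 ± 0.30 for NFKB2.

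Lists of other functions also shifted in this contrast, of which the ribosomal, oxidative phosphorylation, erythroid and granule lists differed with the library mark as given above. Of the ribosomal protein genes 44 of 44 were higher (median 0.71, adjusted p = 4.26e-10), and 41 of 51 nuclear-encoded oxidative phosphorylation genes were higher (0.41, adjusted p = 0.00105). Of the cell and granule genes, 18 of 20 erythroid markers were higher (0.41, adjusted p = 0.0209), and 7 of 8 granule genes were higher (0.69, adjusted p = 0.05). Of the 12 genes of the mitochondrial genome, 11 were lower (−0.61, adjusted p = 0.00818). None of the 5 lists had a gene called over all genes or adjusted over the list alone, and each had adjusted p = 0.918 with an estimated correlation. With the mark as covariate the adjusted p was 0.123 for ribosomal, 0.878 for oxidative phosphorylation, 0.958 for erythroid and 0.958 for granule genes. The mitochondrial list had a median difference of 0.01 between the marks, and with the mark as covariate its median was −0.63 and its adjusted p = 3.15e-05 (0.86 with an estimated correlation). Without letter B it was 0.79 for oxidative phosphorylation, 0.402 for erythroid and 0.107 for granule genes. Without letter E it was 0.0916 for mitochondrial and 0.153 for granule genes. With H left out it was 0.0818 for mitochondrial genes, and without L it was 0.106 for erythroid and 0.24 for granule genes. The other 25 lists missed the threshold (lowest adjusted p = 0.0592). Among them were glycolysis (median 0.08, adjusted p = 0.726), pyruvate dehydrogenase and its regulators (−0.25, adjusted p = 0.421) and the TCA cycle (−0.22, adjusted p = 0.874).

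The count of called genes depended on single libraries. It was 42 without control H, 11 without letter H and 10 without letter L. It was 5 in the libraries with mark r alone, where SE had only SE E.

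To determine what the bacteria changed in blood that also held DCA, SE+DCA was compared with DCA. The 8 called genes all rose and were CSF1, CCL3L1, CCL4, G0S2, GPR84, IER3, NFKBIA and DUSP2. CSF1 rose from 0.113 ± 0.179 to 7.2 ± 3.9 CPM (SD, n = 4; log2 6.06 ± 0.69, adjusted p = 8.09e-05), with 4 counts in the DCA libraries. GPR84 rose from 1.07 ± 0.464 to 12.2 ± 4.88 CPM (log2 3.48 ± 0.38, adjusted p = 6.48e-05) and G0S2 from 0.521 ± 0.474 to 11.7 ± 8.21 CPM (log2 4.47 ± 0.59, adjusted p = 4.53e-04). CCL3L1 rose by 5.23 ± 0.68, CCL4 by 3.39 ± 0.48, IER3 by 2.42 ± 0.36, NFKBIA by 2.22 ± 0.35 and DUSP2 by 1.74 ± 0.33 (log2, adjusted p = 4.53e-04, 8.04e-04, 0.00112, 0.00245 and 0.0297), each in 4 of 4 letters. DUSP2 was lost in 13 of 29 settings (adjusted p up to 0.635), among them each letter left out, while NFKBIA was lost in 3, IER3 in 2 and CCL3L1 in 1. CSF1 was left out of the largest rises under the rule because of its mean level, and comes under it as a member of the proinflammatory list.

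The 8 genes were also among the 17 that rose with SE in the absence of DCA, where 0.018 shared genes were expected for independent calls. The pair of contrasts had no library in common. They shared the pig letters and the estimate of the spread, so the calls were not independent. At an unadjusted p under 0.05 there were 128 genes, fewer than the 378 expected by chance. Of 8 proinflammatory genes 3 rose, 5 adjusted over the list alone. The median was 2.47 (adjusted p = 2.28e-29, adjusted p = 1.16e-04 with an estimated correlation). Of 18 feedback inhibitors 2 rose, 7 adjusted over the list alone. The median was 0.63 (adjusted p = 2.34e-18, adjusted p = 7.15e-04 with an estimated correlation). Uncalled members were TNFAIP3, an enzyme that ends NF-kB signalling, at 1.74 ± 0.44 and NFKBIZ at 1.94 ± 0.53.

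Of 23 genes of the Toll-like receptor and NF-kB list 17 were higher and none was called over all genes or adjusted over the list alone. The median was 0.28 (adjusted p = 0.00234, adjusted p = 0.0571 with an estimated correlation). The adjusted p was 0.0525 without letter E and 0.124 in the libraries with mark r alone. Of 17 immediate early genes 1 rose, IER3, also adjusted over the list alone, and 12 were higher (0.31, adjusted p = 4.34e-04, adjusted p = 0.648 with an estimated correlation). This list's median was −0.78 in mark a, and its adjusted p was 0.0839 with the mark as covariate. Of 44 ribosomal protein genes 43 were lower (−0.21, adjusted p = 0.004) and of 12 mitochondrial genes 11 were lower (−0.32, adjusted p = 0.0309). In both lists 0 genes were called over all genes or adjusted over the list alone, and adjusted p = 0.918 with an estimated correlation. Those 2 calls were lost with the mark as covariate (adjusted p = 0.736 and 0.14), and without letter E (0.0694 and 0.677). Ribosomal genes also lost it without letter L (0.794) and mitochondrial genes without letter B (0.206) and by library size alone (0.212). The count of called genes was 5 without letter H, and the other 27 lists missed the threshold (lowest adjusted p = 0.0527).

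To determine what DCA changed without bacteria, DCA was compared with control. No gene passed the threshold in edgeR (lowest adjusted p = 0.202), 525 genes had an unadjusted p under 0.05 where 378 were expected by chance (830 with the mark and the crossed block), and DESeq2 called 19. Chemokine and growth factor genes, among the genes with the lowest p, had lower means than in control. CSF1 stood at 0.113 ± 0.179 against 1.19 ± 0.618 CPM (SD, n = 4; log2 −3.40 ± 0.77, adjusted p = 0.202). CCL3L1 stood at 0.294 ± 0.224 against 2.34 ± 1.07 (−2.88 ± 0.68, adjusted p = 0.279) and CCL4 at 1.11 ± 0.712 against 4.17 ± 1.65 (−1.87 ± 0.47, adjusted p = 0.327), each lower in 4 of 4 letters. FOS, a subunit of the AP-1 transcription factor, had 3.28 ± 0.841 against 12.3 ± 7.56 CPM (−1.90 ± 0.41, adjusted p = 0.202). With the mark and the crossed block 10 genes passed, among them CSF1 (adjusted p = 0.0163) and CCL3L1 (0.0455). DESeq2 gave 0.0322 for CSF1, 0.0162 for CCL3L1 and 0.0328 for CCL4. Over its settings CSF1 passed in 4 of 28 (adjusted p from 8.58e-05 to 0.999), CCL3L1 in 4 of 29 (1.96e-05 to 0.87) and CCL4 in 3 of 29 (0.00651 to 0.999).

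Over the proinflammatory list, 0 of 8 genes passed over all genes and 3 fell adjusted over the list alone. Of the 8 genes 7 were lower (median −0.88, adjusted p = 7.27e-04, adjusted p = 0.134 with an estimated correlation). Of 23 Toll-like receptor and NF-kB genes 17 were lower (median −0.35, adjusted p = 0.0122, adjusted p = 0.148 with an estimated correlation). Values were −1.75 ± 0.53 for the adaptor TRAF6, −0.79 ± 0.25 for the NF-kB subunit RELA and −1.64 ± 0.67 for TLR4, with 0 called adjusted over the list alone. This call was lost without letter E (adjusted p = 0.369), and the list's median was −0.41 in mark a. Of 15 heat shock and chaperone genes 13 were higher (median 0.38, adjusted p = 0.004, adjusted p = 0.371 with an estimated correlation, and 0.0607 without letter H). Here 0 genes were called over all genes or adjusted over the list alone, with values of 0.83 ± 0.29 for HSPH1 and 0.72 ± 0.25 for DNAJA1.

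The 12 genes of the mitochondrial genome were higher in 12 of 12 (median 0.42, adjusted p = 0.0222) and ribosomal protein genes in 42 of 44 (0.33, adjusted p = 5.68e-05). In both 0 genes were called over all genes or adjusted over the list alone, and each list had adjusted p = 0.918 with an estimated correlation. Without letter E these were lost (adjusted p = 0.44 and 0.613), and without letter L that of mitochondrial genes (0.116). The metabolic lists missed the threshold. Medians were −0.02 for glycolysis (adjusted p = 0.876), 0.02 for pyruvate dehydrogenase and its regulators (0.881), −0.00 for the TCA cycle (0.952) and −0.03 for nuclear-encoded oxidative phosphorylation (0.881). The lowest p within them belonged to PFKFB4, a regulator of glycolytic flux, at −1.25 ± 0.45 (adjusted p = 0.59), and to UQCRFS1 of respiratory complex III at −1.18 ± 0.35 (adjusted p = 0.448). The other 28 lists had a lowest adjusted p of 0.151, and the count of genes was 1 without DCA L.

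To determine what DCA changed in blood exposed to the bacteria, SE+DCA was compared with SE. No gene passed the threshold in edgeR (lowest adjusted p = 0.0569, NFKBIE), 1063 genes had an unadjusted p under 0.05 where 378 were expected by chance, and DESeq2 called 122. With the mark, which differs between these groups, as covariate 366 genes had such a p, and with the mark and the crossed block 368, each below the 378. As a group, the proinflammatory genes were lower with DCA in 7 of 8, of which 0 passed over all genes and 6 adjusted over the list alone. The median was −1.80 (adjusted p = 3.44e-06, adjusted p = 0.0229 with an estimated correlation). Mark a was found in 3 of the 4 SE libraries and 0 of the SE+DCA libraries. Over the 8 genes the difference between the marks had a median of 0.04 (SD 1.13). With the mark and the crossed block the median was −1.65, with adjusted p = 2.05e-05 and adjusted p = 0.122 with an estimated correlation. CCL4 had 12.1 ± 6.63 CPM with DCA against 40 ± 8.32 without (SD, n = 4; log2 −1.73 ± 0.42, adjusted p = 0.132), and CSF1 7.2 ± 3.9 against 21.9 ± 9.77 CPM (−1.61 ± 0.44, adjusted p = 0.139). CCL5, a chemokine of T cells and monocytes, had −1.90 ± 0.49 (adjusted p = 0.137) and CCL2 −2.71 ± 0.73 (adjusted p = 0.139). CCL5 was 1.43 ± 0.39 higher in mark a (adjusted p = 0.0208), and with the mark as covariate it had −0.63 (adjusted p = 0.984, and 0.00111 to 1 over its settings). CCL4, CSF1 and CCL2 were lower in 4 of 4 letters and CCL5 in 3. With DESeq2 CCL4 had adjusted p = 0.00879 and CSF1 0.0351. Over its settings CCL4 passed in 5 of 29 (0.0024 to 1) and CSF1 in 3 of 29 (0.00732 to 1).

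Other genes that SE had raised differed in size. NFKBIE had −1.55 ± 0.28 (adjusted p = 0.0569). The means of NFKBIA were 63.7 ± 25.4 against 63.8 ± 9.27 CPM (SD, n = 4). Those of DUSP2 were 52.1 ± 25.4 against 64.1 ± 11.2 and those of IER3 12.5 ± 4.83 against 14.9 ± 3 CPM. SE+DCA H had 101 CPM of NFKBIA and 90 of DUSP2, against 44.5 to 59.8 and 35.4 to 42.4 in the rest of that group. NFKBIA was lower with DCA in letters E and L and higher in B and H, so its equal means do not show an unchanged gene. The receptor TLR2 had 0.394 ± 0.447 against 2.31 ± 0.63 CPM (−2.61 ± 0.78, adjusted p = 0.157), and IRAK1, a kinase downstream of it, −1.24 ± 0.33 (adjusted p = 0.139). Among 15 heat shock and chaperone genes 13 were higher (median 0.50, adjusted p = 0.00427, adjusted p = 0.371 with an estimated correlation). Of these 0 passed over all genes and 3 adjusted over the list alone, which were HSPH1 (1.24 ± 0.30), DNAJA1 (0.96 ± 0.25) and HSPA5, the chaperone of the endoplasmic reticulum (0.87 ± 0.30). The adjusted p of this list was 0.0585 with the mark and the crossed block. The call was also lost in the libraries with mark r alone, where SE had only SE E.

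Genes of the mitochondrial genome were higher in 12 of 12 (median 0.60, adjusted p = 0.004), with 1.31 ± 0.41 for ND4, a subunit of complex I. Nuclear-encoded oxidative phosphorylation genes were lower in 46 of 51 (−0.71, adjusted p = 1.04e-04). In both lists 0 genes were called over all genes or adjusted over the list alone, each with adjusted p = 0.918 with an estimated correlation. The first call was lost without letter E (adjusted p = 0.0771), and the second with the mark as covariate (adjusted p = 0.0863). Ribosomal protein genes were lower in 42 of 44 (median −0.61, adjusted p = 1.97e-04, adjusted p = 0.918 with an estimated correlation). With the mark as covariate they were higher instead (median 0.32, adjusted p = 4.06e-04), and without letter B the adjusted p was 0.444. Medians were −0.15 for glycolysis (adjusted p = 0.863), 0.24 for pyruvate dehydrogenase and its regulators (0.767) and 0.05 for the TCA cycle (0.901). The other 28 lists had a lowest adjusted p of 0.0748. The count of called genes was 85 without SE E, the SE library with mark r, 2 without letter E, 3 without letter H and 2 without SE+DCA E.

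**Figure D3:**
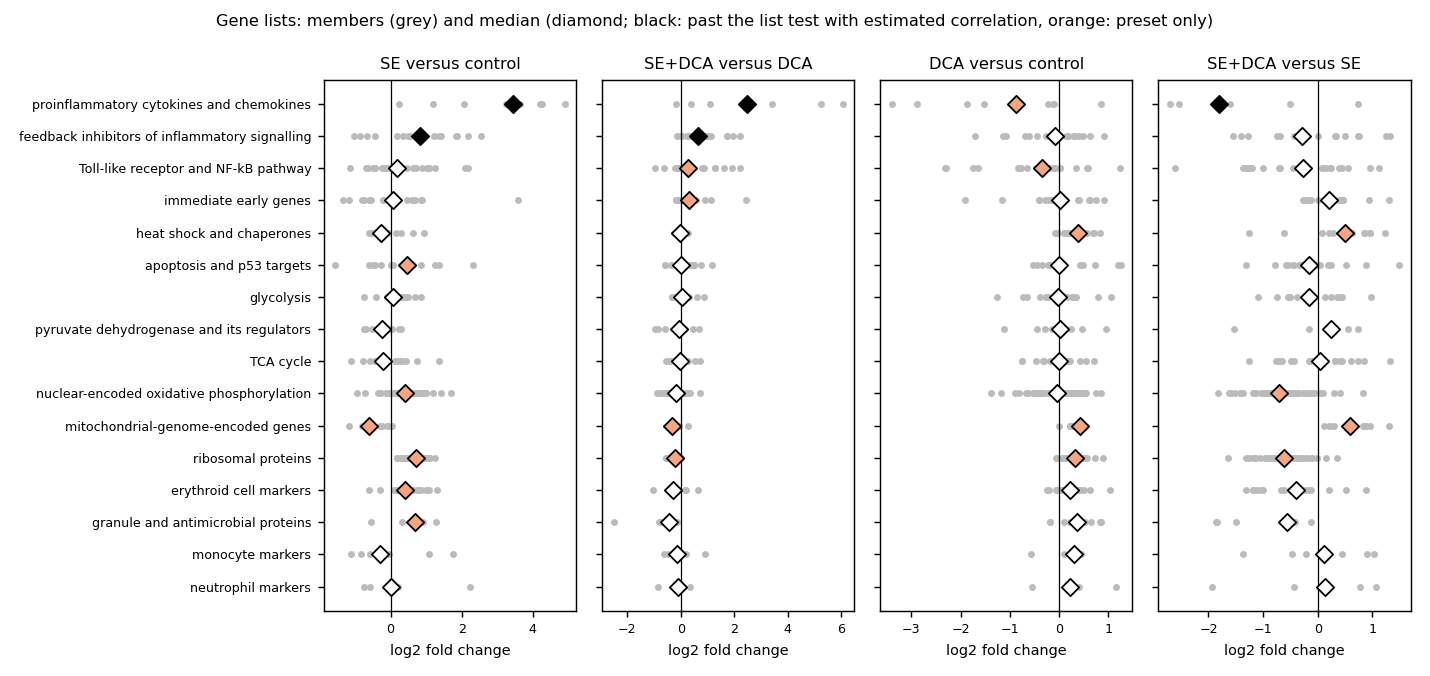
Log2 fold changes of the tested members of 16 gene lists (grey points) with the list median (diamonds) in the 4 contrasts between groups. Black diamonds passed the list test with an estimated correlation, orange ones only with the preset correlation, and white ones in neither, and the horizontal axes differ in range between contrasts. The proinflammatory list had medians of 3.45 for SE versus control, 2.47 for SE+DCA versus DCA, −0.88 for DCA versus control and −1.80 for SE+DCA versus SE.

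To determine whether the response to the bacteria differed with DCA, the interaction was tested. No gene passed (lowest adjusted p = 0.892), 282 genes had an unadjusted p under 0.05, fewer than the 378 expected by chance (995 without letter H, 1094 without control H), and DESeq2 called 0. Adjusted over the list alone, NFKBIE passed in the feedback list (adjusted p = 0.0329). The interaction was 1.80 ± 0.91 for CSF1, −1.40 ± 0.39 for NFKBIE, −1.67 ± 0.69 for CCL5 and −1.17 ± 0.49 for IER3 (log2, each adjusted p = 0.892). The list test called ribosomal protein genes (44 of 44 lower, median −0.94, adjusted p = 1.79e-13) and oxidative phosphorylation genes (40 of 51 lower, −0.66, adjusted p = 5.68e-05). It also called erythroid markers (18 of 20 lower, −0.63, adjusted p = 9.34e-04) and granule genes (8 of 8 lower, −1.19, adjusted p = 0.0022). In the 4 lists 0 members were called over all genes or adjusted over the list alone. Granule genes had adjusted p = 0.905 with an estimated correlation, and the other 3 lists adjusted p = 0.918 with an estimated correlation. The medians of these lists were 1.04, 1.03, 0.58 and 1.03 higher in mark a, and with the mark as covariate the adjusted p was 0.65, 0.422, 0.937 and 0.878. Without letter L that of oxidative phosphorylation was 0.0731, and without letter E that of granule genes was 0.0771.

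Over the 5 contrasts, the list calls that held with an estimated correlation were those of 2 lists. They were the proinflammatory list in SE versus control, SE+DCA versus DCA and SE+DCA versus SE, and the feedback list in SE versus control and SE+DCA versus DCA. Of the cell type lists, neutrophil, monocyte, T cell, B cell and platelet markers were not called in any of the 5 contrasts. In SE+DCA versus SE 2 of 17 T cell markers were higher and 4 lower adjusted over the list alone, with 1 higher and 1 lower for both B cell and monocyte markers. In fry's test for change in either direction the T cell list had adjusted p = 0.00369 and the B cell list 0.0449. In SE versus control 1 monocyte marker was lower and 1 B cell marker higher adjusted over the list alone. The NK cell, eosinophil and dendritic cell lists had fewer than 4 tested members and were not tested.

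Of the genes fixed in advance, IL6 had 9 counts in total, which came from the SE group, IL10 had 4, IFNG had 2 and PDK4 had 0, and these were not tested. CXCL8, an attractant of neutrophils, had 88 counts and was not tested. It stood at 1.33 ± 1.28 CPM in SE and 0.484 ± 0.191 in SE+DCA against 0.1 ± 0.201 in control (SD, n = 4). LDHA, which makes lactate, had log2 values of −0.10 ± 0.30 for SE versus control, 0.32 ± 0.30 for DCA versus control and 0.36 ± 0.30 for SE+DCA versus SE (adjusted p = 0.908, 0.937 and 0.57). HK2, the inducible hexokinase, had 0.44 ± 0.63, 0.80 ± 0.62 and 0.98 ± 0.62 (adjusted p = 0.817, 0.902 and 0.463). PDK1, a target of DCA, had −0.28 ± 0.39, 0.15 ± 0.38 and 0.24 ± 0.39 (adjusted p = 0.81, 0.989 and 0.777). LDHA and HK2 also differed with the library mark. SE E, with mark r, had 38.9 CPM of LDHA and 3.59 of HK2. The SE libraries with mark a had 19.6 to 22.3 and 0.416 to 0.944 CPM. Control H and DCA E, with mark a, had the lowest LDHA of their groups (17.9 and 26.2 CPM). For these 2 genes the contrasts with the SE group therefore cannot part the treatment from the mark. In SE+DCA versus DCA, TLR2 had 1.90 ± 1.01, LDHA −0.06 ± 0.30, HK2 0.62 ± 0.61 and PDK1 −0.19 ± 0.39 (adjusted p = 1 each). Their interaction was −0.28 ± 1.97, 0.05 ± 0.42, 0.18 ± 0.88 and 0.09 ± 0.55. TLR2 had −2.32 ± 0.96 in DCA versus control (adjusted p = 0.651).

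To compare the effect of DCA with and without bacteria, the log2 fold changes of both contrasts were set against each other across 7569 genes, which are not independent replicates. Pearson's r was 0.28 and Spearman's rho 0.26, and 57.7% of the genes had the same sign. With the contrasts taken from different letters, r averaged 0.19 over 6 ways and ran from −0.22 to 0.39. These ways follow the letters of the titles. If those of DCA B and DCA E were exchanged, some ways would share an animal. With the mark and the crossed block r was 0.21. To measure how much of the SE response was kept with DCA, genes chosen in 2 letters of the titles were measured in the other 2, without a test. The ratio of the mean response with DCA to that without averaged 0.44 over 6 ways and ran from −0.64 to 0.79. The choice in letters B and L, whose SE libraries had mark a and whose controls had mark r, picked 1486 genes and gave −0.64. In the other 5 ways, with 18 to 52 genes, the ratio averaged 0.66 and ran from 0.45 to 0.79. With genes chosen by adjusted p, 4 ways picked genes (6 to 1480) and the ratio averaged 0.50, from −0.65 to 1.04. Beside −0.65 for letters B and L it was 0.77 for B and H (6 genes), 1.04 for E and L (6 genes) and 0.83 for H and L (9 genes).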

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

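The tests on the mark, on gene length, on the letters of the DCA libraries and on the lower proinflammatory genes, as well as the averaged contrasts, were chosen only after the result was seen. In 136 groups of 4 libraries, 17 had a library far from the other 3, where 1 in 20, or 6.8, is expected for independent normal values. Where the other 3 values were 0, any count stood out. This was so for IL1A and CCL2 in DCA B (3 and 2 counts) and ENSSSCG00000039214 in DCA B and control E (6 and 14 counts). The 17 therefore cannot be set against the 6.8 as a test.

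The first pattern was the spread of the libraries on the first principal component, where those with mark a scored from 14.9 to 83.9 and those with mark r from −50.5 to 12.1, with no wide gap between them. Exposure to SE as the whole cause is argued against, as within mark r the 5 exposed libraries scored 11.3 above the 6 others (SD 18.6), where the marks differed by 69.8. The mark remains open, as its difference on this component had an exact permutation p = 2.29e-04, and the rank correlation across genes between the difference of the marks and gene span was −0.37 over 6437 genes (85% of those tested). Genes higher in mark a had a median span of 9218 bases and those lower in mark a 58745, against 28598 for the tested genes. A library batch that favours short genes may account for a part of the spread, which remains a hypothesis since the meaning of the mark is not given in the sources used here.

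The second pattern was that, of the 12 genes that part the letters B and E in the other 3 groups, 11 placed DCA B with letter E and 11 placed DCA E with letter B. An example is PRR13, with a mean log2 CPM of 7.71 in the other B libraries and 3.37 in the other E libraries, against 2.76 in DCA B and 8.41 in DCA E. In the other 46 placements 39.3 to 100% of the genes stood with the library's own letter, under 50% for SE B against H (22 of 56, while SE H had 44 of 56 against B) and DCA E against L (3 of 7). A response to DCA shared by the 4 animals is argued against, as in DCA H and DCA L these genes differed from their own letter by a median of 0.57 (SD 0.74, log2, size without sign), against 3.74 in DCA B and DCA E. A response to DCA in these 2 animals alone could also appear in SE+DCA B and SE+DCA E, which held DCA too. PRR13 had 2759 and 68 counts there, near control B and control E (2112 and 145). DCA B and DCA E had 88 and 3776 counts. The SE+DCA libraries helped to pick these genes, so they cannot decide it, and such a response stays open. An exchange of the letters of these 2 DCA libraries may account for the pattern, which would leave the groups as they are. With the letters exchanged the block gave 20 genes in SE versus control.

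The third pattern was the lower level of proinflammatory genes in SE+DCA than in SE. Fewer monocytes and neutrophils are argued against, as the median of 11 of their markers was 0.13 (SD 0.99, from −1.93 to 1.06), where a loss of cells would lower them by about the list's median of −1.80. The mark as the whole cause would need a difference of 2.40 between the marks, as 3 of 4 SE and 0 of 4 SE+DCA libraries had mark a. The members differed by a median of 0.04 (SD 1.13, from −1.58 to 1.62). This estimate takes the mark to act alike in each group, and in exposed blood it rests on SE E alone. Without SE it rests on control H and DCA E, in groups where IL1A had 4 and 3 counts. It therefore cannot decide whether the mark was the whole cause. For a part of the change the mark cannot be told apart from DCA: with the mark and the crossed block the median was −1.65 (SD of the members 1.42, against 1.13 without), and the call with an estimated correlation ended at adjusted p = 0.122 (0.0229 without them, 0.0428 with the mark alone) as the estimated correlation went from 0.0639 to 0.122 and the residual degrees of freedom from 12 to 8. The effect of DCA itself stays open.

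The splits below left the letters aside, so for libraries paired by animal they cannot exclude chance. Only 8 of the 35 part each letter, too few for a share under 0.05. Among the counts of called genes, only the real split of 35 in SE+DCA versus DCA gave as many as 8 (highest other 1, and 0 among the 8 splits). This share of 1 of 35 lay under 0.05 and is the smallest that 35 splits can give. For SE versus control 2 of 35 splits gave as many as 18, so chance was not excluded. The other split set SE B, SE H, SE L and control H, the libraries with mark a, against the rest and called 1836 genes, which points to a structure of the samples. Among the 8 splits that part each letter the highest other was 0, where the others mix treated and untreated libraries, and with the mark as covariate the count was 15. A real count of 0 is reached by any split, so the 35 of 35 for DCA versus control (highest other 0), the 35 of 35 for SE+DCA versus SE (highest other 1) and the 100 of 100 drawn for the interaction (highest other 480) say nothing about chance. For SE averaged over blood with and without DCA 5 of 100 drawn splits gave as many as 24 (highest other 2465), so chance was not excluded. For DCA averaged over blood with and without SE 2 of 100 gave as many as 85 (highest other 527), a share under 0.05 with the letters left aside.

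The mean of the proinflammatory list was 2.97 in SE versus control (1 of 35 splits, highest other 1.59), 2.61 in SE+DCA versus DCA (1 of 35, highest other 2.06) and −1.52 in SE+DCA versus SE (1 of 35, highest other 1.19). In these 3 the share lay under 0.05 and was the smallest that 35 splits can give, but with the letters left aside chance was not excluded. The share was not under 0.05 for −1.16 in DCA versus control (2 of 35, highest other 1.25). In SE+DCA versus SE the next 4 means, −0.91 to −1.19, came from the 4 other splits with every mark a library on 1 side. Among the 8 splits that part each letter, too few for a share under 0.05, the highest other was 1.47 beside 2.97, 1.66 beside 2.61, 0.91 beside −1.52 and 0.69 beside −1.16. These 8 follow the letters of the titles. With the letters of DCA B and DCA E exchanged, a split at −2.06 in SE+DCA versus DCA also parts each letter.

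The libraries far from their group were these, with the values of the other 3 in brackets. The most abundant gene took 67.5% of counts in DCA E (78.2 to 79.9%). In SE B haemoglobin genes took 32.9% of the remaining counts (16.3 to 18.9%), the TMM factor was 0.465 (1.1 to 1.22), and NFKBIA stood at 50 CPM (67.3 to 69.7). Reads assigned to more than 1 gene took 50.3% in SE+DCA E (43.4 to 44.1%). In control E, GPR84 stood at 2.14 CPM (0.975 to 1.03) and ENSSSCG00000039214 at 0.937 CPM (0). In DCA B, IL1A stood at 0.224, CCL2 at 0.15 and ENSSSCG00000039214 at 0.449 CPM (0 in each case). In SE E, HK2 stood at 3.59 CPM (0.416 to 0.944) and LDHA at 38.9 CPM (19.6 to 22.3). PDK1 stood at 6.08 CPM in DCA L (2.88 to 3.42), and CCL2 at 4.21 CPM in SE H (1.08 to 1.49). In SE+DCA H, CCL3L1 stood at 27.9 CPM (5.19 to 7.99), DUSP2 at 90 CPM (35.4 to 42.4) and NFKBIE at 5.55 CPM (4.02 to 4.19).

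The response to SE differed with DCA by the interaction test for 4 lists: nuclear-encoded oxidative phosphorylation (median −0.66, adjusted p = 5.68e-05), granule and antimicrobial proteins (−1.19, adjusted p = 0.0022), ribosomal proteins (−0.94, adjusted p = 1.79e-13) and erythroid markers (−0.63, adjusted p = 9.34e-04). With an estimated correlation none of the 4 passed, with adjusted p = 0.918, 0.905, 0.918 and 0.918. These lists were 1.03, 1.03, 1.04 and 0.58 higher in mark a, and with the mark as covariate the 4 calls ended (adjusted p = 0.422, 0.878, 0.65 and 0.937).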

How the results depend on the processing

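The settings chosen after seeing the data were the crossed block, the mark with that block, the libraries of 1 mark alone, removal of the most abundant gene and the averaged contrasts. No called gene changed direction in any setting run. GPR84 and G0S2 in both SE contrasts, and CSF1 and CCL4 in SE+DCA versus DCA, passed in each setting run, while 20 of the 26 calls were lost in at least 1. With 9, 4, 2 and 88 counts, IL6, IL10, IFNG and CXCL8 did not pass the filter and were not tested. Where not stated otherwise, the cause was not tested.

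For SE versus control, 18 genes became 32 with DESeq2, 240 with DESeq2 and the block, 7 by library size alone, 32 without a filter, 11 with only the 2 groups, 5 with mark r alone and 4 with mark a alone (fewer samples, with a lone SE or control library assumed to vary like the others). For DCA versus control, 0 became 19 with DESeq2, 227 with DESeq2 and the block, 6 without a filter, 20 with the haemoglobin share and 10 with the mark and crossed block. For SE+DCA versus SE, 0 became 122 with DESeq2, 327 with DESeq2 and the block, 76 without a filter, 2 with a stricter filter and 2 at adjusted p under 0.10. For SE+DCA versus DCA, 8 became 189 with DESeq2 and the block and 5 by library size alone. The interaction went from 0 to 61 with DESeq2 and the block.

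SE averaged went from 24 to 89 with DESeq2 and the block, 10 by library size alone, 40 with the mark and crossed block and 10 with mark r alone. DCA averaged went from 85 to 50 with the block, 340 with DESeq2 (155 higher, 185 lower), 344 with DESeq2 and the block, 1 by library size alone, 192 without a filter, 268 at adjusted p under 0.10, 20 with the mark, 196 with the haemoglobin share, 151 with the crossed block, 21 with the mark and crossed block and 0 with mark r alone. Library size alone moved the median of all genes to −0.38 in SE versus control, −0.32 in DCA versus control, 0.20 in SE+DCA versus SE, 0.19 in SE+DCA versus DCA and 0.58 in the interaction, and fold changes are relative to the TMM scaling.

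Leaving out letters or libraries gave 10 to 42 genes in SE versus control, 0 to 1 in DCA versus control, 0 to 85 in SE+DCA versus SE, 5 to 8 in SE+DCA versus DCA, 12 to 27 in SE averaged and 0 to 244 in DCA averaged. With the block it gave 6 to 21, 0 to 0, 0 to 81 and 5 to 9 in the first 4. The ribosomal list reversed in SE+DCA versus SE from adjusted p = 1.97e-04 to 4.06e-04 with the mark, 0.00259 with the mark and crossed block and 0.0163 with mark r alone.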

Other observations

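The averaged contrasts were chosen only after the result was seen. With the 8 libraries with DCA set against the 8 without, by the mean of DCA versus control and SE+DCA versus SE, edgeR called 85 genes, 25 higher and 60 lower, and 21 with the mark and the crossed block, of which 17 were shared. Among these 17, the chemokines CCL4 and CCL3L1 and the growth factor CSF1 fell by 1.80 ± 0.32, 2.37 ± 0.43 and 2.51 ± 0.44 (log2 ± s.e., adjusted p = 0.0132, 0.0175 and 0.0132). CCL4 had 22.1 ± 19.9 CPM without and 6.59 ± 7.31 CPM with DCA (SD, 8 libraries each). CXCR4, the receptor that holds leukocytes in the marrow, fell by 0.87 ± 0.21 and BMF, a gene that promotes cell death, by 1.11 ± 0.19 (adjusted p = 0.0446 and 0.012). DNAJA1, a co-chaperone, rose by 0.84 ± 0.18, PLK2, a stress-induced kinase, by 2.06 ± 0.40, and TDP2, an enzyme of DNA repair, by 1.38 ± 0.21 (adjusted p = 0.0273, 0.0185 and 0.0117).

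In this averaged contrast the proinflammatory list had a median of −1.57 (adjusted p = 4.34e-06, adjusted p = 0.0248 with an estimated correlation) with 3 of 8 genes called as lower over all genes. With the mark and the crossed block the median was −1.75 (adjusted p = 0.0485 with an estimated correlation). Heat shock genes had a median of 0.42 with 2 of 15 called as higher over all genes (adjusted p = 5.16e-04, adjusted p = 0.113 with an estimated correlation). Also past the threshold were the Toll-like receptor and NF-kB list (−0.19, adjusted p = 0.00765, 0.087 with an estimated correlation), nuclear-encoded oxidative phosphorylation (−0.34, 0.0258, 0.833) and mitochondrial genes (0.42, 0.00108, 0.691). With the mark and the crossed block the Toll-like receptor and NF-kB list had −0.39 (adjusted p = 0.0485 with an estimated correlation), mitochondrial genes 0.57 (0.315) and heat shock genes 0.29 (0.245), while oxidative phosphorylation turned to 0.13 (0.823). The count of 85 was lower without each letter (2 without B, 31 without E, 21 without H and 0 without L). It was 24, 23 and 39 without DCA B, DCA H and DCA L, 45, 29 and 14 without SE B, SE H and SE L, 27, 40 and 21 without SE+DCA B, SE+DCA H and SE+DCA L, 31 and 44 without control E and control L, and 244 without SE E. It was 0 in the libraries with mark r alone, with 778 genes at an unadjusted p under 0.05.

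With the 8 libraries with SE set against the 8 without, 24 genes rose, and 40 with the mark and the crossed block, which included the 24. The genes beyond those called in the separate contrasts were ZC3H12A, an RNase that degrades cytokine transcripts (1.23 ± 0.22, adjusted p = 0.0061), TNFAIP3 (1.57 ± 0.30, adjusted p = 0.0127), NFKBIZ (1.88 ± 0.37, adjusted p = 0.0201), GADD45B (1.07 ± 0.22, adjusted p = 0.0302), RRAD, a small GTPase (2.71 ± 0.49, adjusted p = 0.00768), SPHK1 (1.15 ± 0.25, adjusted p = 0.0418), MARCKS (1.08 ± 0.24, adjusted p = 0.047) and ENSSSCG00000001404 (1.38 ± 0.28, adjusted p = 0.0242). The Toll-like receptor and NF-kB list had a median of 0.23 (adjusted p = 4.63e-04, adjusted p = 0.00871 with an estimated correlation). The proinflammatory list had 3.19 (adjusted p = 6.74e-47, 3.70e-06 with an estimated correlation) and the feedback list 0.75 (2.46e-23, 8.77e-05). Past the threshold only with the preset correlation were platelet markers (0.43, adjusted p = 0.00268, 0.637 with an estimated correlation), ribosomal proteins (0.25, 0.00192, 0.765), mitochondrial genes (−0.37, 4.09e-04, 0.637), immediate early genes (0.01, 0.00254, 0.637) and apoptosis and p53 targets (0.19, 0.0073, 0.0722). With the mark and the crossed block the 8 medians kept their direction. The proinflammatory, feedback and Toll-like receptor lists then had adjusted p = 4.01e-05, 3.94e-04 and 0.0227 with an estimated correlation, and the other 5 missed the threshold. The count was 15 without letter B, 15 without E, 12 without H and 12 without L.

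Libraries that share a letter correlated by a mean of 0.10 in their deviations from the group means (24 pairs, from −0.45 to 0.58), against −0.03 for other pairs, and 9 libraries correlated best with their own letter. With the letters of DCA B and DCA E exchanged the mean was 0.16 (from −0.20 to 0.58) and 12 libraries did so.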
